A study of Sus scrofa with 6 samples.

How the data were processed

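Total RNA from renal cortex of 3 control and 3 ischemia kidneys was extracted with a column kit that removes genomic DNA and labelled with Cy3 by the Low Input Quick Amp method, per the labels. Each sample was hybridised to 1 array of 43803 spots. The deposited scanner files hold spot intensity, which per the file headers was background-subtracted and spatially detrended by Agilent Feature Extraction within each array, with no scaling between arrays. The headers name version 10.10.1.1 of that program, whereas the submitters' processing notes name 11.5.1.1, with R 2.15.2 and limma. The authors' deposited value table is on the log2 scale. Its 36796 values per array followed the log2 median spot signal (Spearman correlation 0.992 to 0.993 within an array), and its column medians were 5.91 to 5.99. How the authors normalized it between arrays, and how they combined several probes of a gene name, is not given in the sources used here. The table was therefore used only as an alternative.

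The main values were log2 of the processed signal minus the 75th percentile of each array, without control spots and spots marked as outliers, averaged over replicate spots of a probe. Probes were kept where the signal was well above background on at least 3 of the 6 arrays and where at least 5 arrays had a value, the latter a rule added during the analysis. This left 25017 of 43603 probes. No spot was saturated. Gene symbols came from the array design's names, updated through a gene table, and from accessions, gene numbers and descriptions in the files. For members of the fixed lists, full gene names in the descriptions were used as well (77 probes). Naming was complete before any group difference was computed. In all 12459 probes received a symbol and 31144 did not, so most of the array is described only as probe counts. A gene was represented by its brightest probe over all 6 arrays, and 2933 genes had more than 1 probe. No genome was used and no coordinates are given.

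Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probes tested. Differences are ischemia minus control. Where a probe was not well above background on any array of a group, the fold is a lower bound. It sets the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. This bound leaves the spread between arrays out. For PRM2, CPLX3 and CCNB2 it equalled the plain fold, so it is not given as a bound for them. Lists of pathway genes and cell type markers, 31 in all, were tested with camera at a preset correlation of 0.01, with adjustment over the 29 lists of at least 3 tested members. A list's shift is the mean difference of its members minus that of all other genes. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so none is given for single genes. The design, the lists, the naming rule and the alternatives were fixed before the data were examined, except where a choice is described as added or chosen later.

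The text names the 10 genes of smallest unadjusted p in each direction, since no gene passed, members of each list by smallest p, and 10 genes chosen in advance for ischemic injury. The rule allowed up to 4 members of each list. After the results were seen, 4 were named for the lists that passed and 2 for the others. Probe A_72_P162751, and the members that passed over their list alone, are reported because the counts were small. PTPRC and CD14 were named after their values were seen. Values of 3 genes that the rule would name are not reported here.

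Each of the 3 slides carried 1 control and 1 ischemia array, so slide could be used as a block. All control arrays lay at position 4 of their slide and all ischemia arrays at position 3, so position and group cannot be told apart. The labels state that the kidneys came from different pigs. They number the samples 1 to 3 in each group. No array pair was a duplicate (correlations of 0.960 to 0.983 between arrays). Alternatives were median centring, quantile normalization, normexp background correction (offset 50), the deposited table, other filters on dim probes, outlier spots kept, slide or sample number as a block, a variance trend, array weights, a 2-fold limit, each array left out in turn, the mean of all probes of a gene, an estimated correlation and fry.

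The procedure was tested on simulated data, in 10 simulations on 24997 probes with 200 changed genes. It recovered 0% of genes changed 1.5-fold or 2-fold and 36.8% of those changed 4-fold, and 7.61 of 100 calls were false. A list shifted by 0.5 was called in 9 of 10 simulations at the preset correlation, 0 of 10 with an estimated correlation and 5 of 10 with fry, and 0 of 280 unshifted lists were called by any of them. The simulated genes varied independently, so these counts do not cover genes that vary together between animals. Values were read and matched in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.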

Results

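Renal cortex RNA was profiled from 6 kidneys of Large White pigs aged 3 months on porcine Agilent arrays, 1 array per kidney. In the control group (n = 3), the kidney was taken out, sampled and frozen without delay. In the ischemia group (n = 3), from other pigs, the vessels were clamped for 60 min at 37 °C, the organ was flushed with cold University of Wisconsin solution (an organ preservation fluid), and it was kept at 4 °C for 24 h before sampling. The comparison asks how cortical RNA differs after warm ischemia, flush and cold storage as 1 sequence. The steps cannot be separated in this design, and no kidney was reperfused. Between 52.6% and 61.4% of the 43803 spots per array were well above background, and this share followed the slide more than the group. It was 52.9% and 52.6% on slide 1, 57.0% and 55.97% on slide 2, and 61.2% and 61.4% on slide 3, with the control array given first each time. The number of arrays limits the precision of every value.

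After ischemia and storage, genes of the proximal tubule, of the antioxidant response and of the mitochondrial genome lay lower as groups, and interferon-stimulated, heat shock, complement and coagulation, and extracellular matrix genes lay higher. These group shifts were small, between 0.23 and 0.42 on the log2 scale in size. Among single genes, EPO, the hormone of red cell production, had a log2 difference of -3.61 ± 0.48 (SE, n = 3 per group), with a signal well above background on only 1 of the 3 ischemia arrays. No gene with a symbol passed the test across all probes, and none of the group shifts passed once the correlation between genes was estimated from these arrays. With that estimate a simulated list shifted by 0.5 was called in 0 of 10 simulations, so this failure does not decide for or against the shifts. Other splits of the 6 arrays into 3 and 3 gave up to 10 lists past the threshold, so the number of such shifts is not particular to ischemia.

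Of 25017 probes tested with limma, 1 passed at a Benjamini-Hochberg adjusted p under 0.05. This probe, A_72_P162751, carried no gene symbol. Its log2 difference was -3.85 ± 0.28 (SE), a signal 14.4-fold lower after ischemia (limma adjusted p = 0.0478), and the differences within the 3 slides were -3.47, -4.37 and -3.72. With slide as a block its limma adjusted p was 0.0560. Among 4251 genes with a symbol, 0 were higher and 0 lower at that threshold, and the smallest limma adjusted p was 0.135. At an unadjusted p under 0.05 there were 161 genes higher and 123 lower, 6.68% of the genes tested. The 3 ischemia values lay beyond all 3 control values in 325 genes above and 179 below, 11.9% of the genes against 10% expected by chance. The 10% takes the 6 arrays as exchangeable and leaves the slides out. With slide as a block, 184 genes were higher and 169 lower at an unadjusted limma p under 0.05. On simulated arrays of the same spread, the procedure recovered 0% of genes changed 2-fold and 36.8% of those changed 4-fold. The balance of higher and lower genes depended on the scaling. At unadjusted p under 0.05 it was 191 against 55 with each array centred on its median, and 739 against 40 in the values the authors deposited. The median log2 difference of all genes was 0.02 with the 75th percentile scaling, 0.17 with median centring and 0.21 in the deposited values.

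The genes with the smallest p in each direction, none of which passed, differed in the same direction on each of the 3 slides. In each of them all ischemia values lay beyond all control values, which fixes the direction on every slide. The agreement is therefore no separate evidence. APOD, a lipid-binding lipocalin, was 4.59-fold higher after ischemia (log2 difference 2.20 ± 0.38 SE, limma adjusted p = 0.387). THBD, the endothelial receptor of thrombin, differed by 1.33 ± 0.27 and VSIG4, a complement receptor of macrophages, by 1.14 ± 0.21. TGFB2, a transforming growth factor, differed by 1.11 ± 0.19, and SLC2A2, the GLUT2 glucose transporter, by 1.08 ± 0.18. The TGFB2 probe was dim, well above background on only 2 of the 3 control arrays. The secreted protease ADAMTS1 differed by 1.05 ± 0.20 and the matrix protein gene MATN2 by 1.03 ± 0.20, and the uncharacterised C1H9orf152 by 1.37 ± 0.28. PRM2 and CPLX3 were not well above background on any control array. Their plain estimates were 2.49-fold and 2.47-fold higher after ischemia. The bound for dim probes equalled these estimates, so the size of both differences is uncertain. Their plain log2 differences were 1.32 ± 0.27 and 1.31 ± 0.27.

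Among the lower genes, MYLPF, a myosin light chain of fast skeletal muscle, had the smallest p (log2 difference -2.34 ± 0.26 SE, limma adjusted p = 0.135). The 3 probes of MYLPF ranged from -2.34 to -0.01. SLC28A1, a sodium-coupled nucleoside transporter, differed by -2.45 ± 0.28 (limma adjusted p = 0.148, or 0.0560 with slide as a block). EPO had a limma adjusted p of 0.272 and was well above background on 3 control arrays and 1 ischemia array, so the size of its difference is uncertain. CD247, the zeta chain of the T-cell receptor, differed by -1.33 ± 0.23. PEBP4 differed by -2.17 ± 0.37, COL1A2, a type I collagen chain, by -1.64 ± 0.30, and PANK1, an enzyme of coenzyme A synthesis, by -1.02 ± 0.20. DUOXA2 differed by -1.85 ± 0.38, F2, the prothrombin gene, by -1.94 ± 0.41, and C4H8orf34 by -0.80 ± 0.18. DUOXA2 was well above background on only 2 of the 3 ischemia arrays. With median centring, MYLPF (limma adjusted p = 0.0394) and EPO (limma adjusted p = 0.00834) passed, and with normexp background correction MYLPF did (limma adjusted p = 0.0372).

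**Figure D1:**
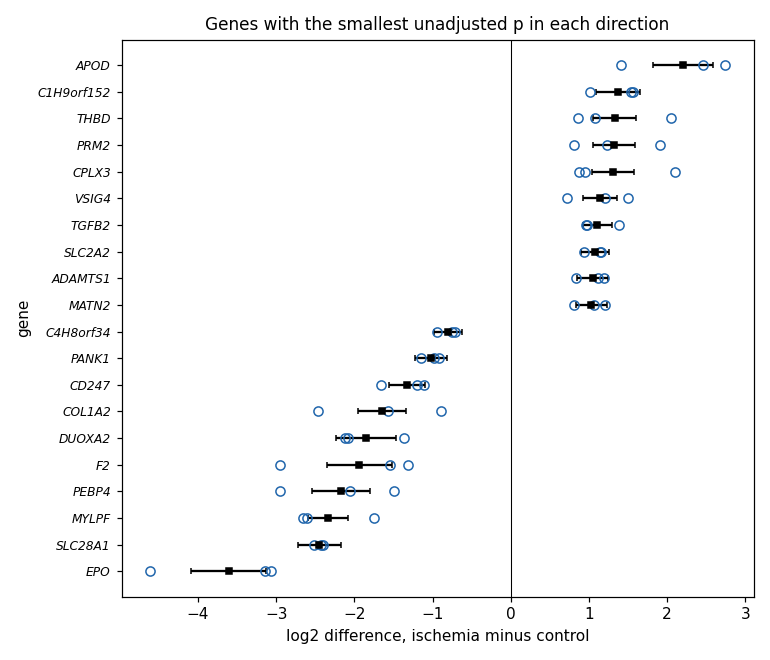
Log2 difference (ischemia minus control, x axis) of the 10 genes with the smallest unadjusted p in each direction (y axis). Squares with bars are the estimate ± SE from 3 arrays per group and open circles the differences within the 3 slides. All circles of a gene lie on its own side of 0, from -4.61 for EPO to 2.74 for APOD, and no gene passed the adjusted threshold. The side follows from the genes shown, whose ischemia values all lie beyond their control values. PRM2 and CPLX3 were not well above background on any control array, so the size of their drawn differences is uncertain.

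Of 29 gene lists fixed before the data were examined and tested with camera at a preset correlation, 7 passed. This count is not particular to the real grouping. Of the 10 splits of the 6 arrays into 3 and 3, 7 gave at least as many lists, the real one included. The proximal tubule list, genes of the nephron segment that reabsorbs most of the filtrate, was lower after ischemia, with 16 of 20 measured members lower. Its mean lay -0.42 from that of the other genes (camera adjusted p = 2.7e-04), and within the slides -0.62, -0.49 and -0.13. SLC22A6, an organic anion transporter, differed by -1.03 ± 0.36 (SE), MIOX, an enzyme of inositol breakdown, by -0.81 ± 0.33, GATM, an enzyme of creatine synthesis, by -0.75 ± 0.30 and the brush border peptidase ANPEP by -0.73 ± 0.28. With an estimated correlation the adjusted p of the proximal tubule list was 0.694. The antioxidant NRF2 targets were lower in 18 of 19 members, with a shift of -0.27 (camera adjusted p = 0.00236) and within-slide shifts of -0.22, -0.45 and -0.15. SRXN1, which repairs oxidised peroxiredoxins, differed by -0.74 ± 0.20, NQO1 by -0.69 ± 0.27, ME1 by -0.61 ± 0.34 and HMOX1, heme oxygenase 1, by -0.56 ± 0.28. SRXN1 was well above background on only 2 of the 3 ischemia arrays. The adjusted p of the antioxidant list was 0.694 with an estimated correlation, and its shift was -0.16 with normexp and quantile normalization (camera adjusted p = 0.0297). The mitochondrially encoded respiratory chain genes were lower in 11 of 12 members (shift -0.26, camera adjusted p = 0.00236), and within slides the shifts were -0.02, -0.33 and -0.42. MT-ND3 differed by -0.48 ± 0.23, MT-CO1 by -0.38 ± 0.20, MT-ND5 by -0.36 ± 0.18 and MT-ATP8 by -0.34 ± 0.18. The adjusted p of the mitochondrial list was 0.844 with an estimated correlation, and with quantile normalization the shift was -0.14 and the call was lost (camera adjusted p = 0.0925).

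Interferon-stimulated genes were higher after ischemia in 15 of 18 members, with a shift of 0.35 (camera adjusted p = 5.2e-04) and within-slide shifts of 0.26, 0.41 and 0.39. OAS2, which senses double-stranded RNA, differed by 0.87 ± 0.29 (SE), the antiviral GTPase MX1 by 0.83 ± 0.26, USP18 by 0.78 ± 0.24 and IFIT1 by 0.60 ± 0.18. With an estimated correlation the adjusted p of the interferon list was 0.694, and in the deposited values its shift was 0.17 (camera adjusted p = 0.0495). Heat shock proteins and co-chaperones were higher in 14 of 16 members (shift 0.27, camera adjusted p = 0.00944), with within-slide shifts of 0.35, 0.26 and 0.20. HSPA8, the constitutive HSP70, differed by 0.60 ± 0.20, HSPH1 by 0.58 ± 0.27, the mitochondrial co-chaperonin HSPE1 by 0.47 ± 0.26 and DNAJB1 by 0.41 ± 0.20. The adjusted p of the heat shock list was 0.694 with an estimated correlation, and its camera adjusted p was 0.0566 without control 1. Complement and coagulation genes were higher in 12 of 20 members (shift 0.28, camera adjusted p = 0.00987), and within slides the shifts were 0.16, 0.26 and 0.41. Besides THBD, the plasminogen activators PLAU and PLAT each differed by 0.76 (SE 0.22 and 0.23) and complement C2 by 0.70 ± 0.23 on its brighter probe and by -0.04 on the other. F2, the prothrombin gene, is outside the fixed list and was lower (-1.94 ± 0.41). The adjusted p of the complement list was 0.694 with an estimated correlation, and its call was lost in the deposited values (camera adjusted p = 0.190). The extracellular matrix list was higher in 15 of 20 members (shift 0.23, camera adjusted p = 0.0309), with within-slide shifts of 0.22, 0.42 and 0.05. The collagen cross-linking enzyme LOX differed by 0.78 ± 0.27 and the basement membrane collagen COL4A1 by 0.47 ± 0.21, against the lower value of COL1A2 in the same list. The adjusted p of the matrix list was 0.694 with an estimated correlation, and its call was lost in 6 other settings, among them leaving out control 1 (camera adjusted p = 0.0630) or ischemia 3 (0.193).

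The directional test of fry, which asks whether a list's genes move one way on balance, passed 0 of the 29 lists. With an estimated correlation, the unadjusted camera p of the 7 lists ran from 0.0278 (heat shock) to 0.233 (mitochondrially encoded). A simulated list shifted by 0.5 was called in 5 of 10 simulations with fry and 0 of 10 with an estimated correlation. Neither failure therefore decides for or against the shifts. With slide as a block, camera passed 11 lists, the same 7 and 4 more. No member of any list passed over all genes tested. Adjusted over the list alone, 2 members of the matrix list passed (TGFB2 and COL1A2), and 1 each of the complement list (THBD), the apoptosis list (CDKN1A), the leukocyte list (CD163) and the fibroblast list (COL1A2).

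**Figure D2:**
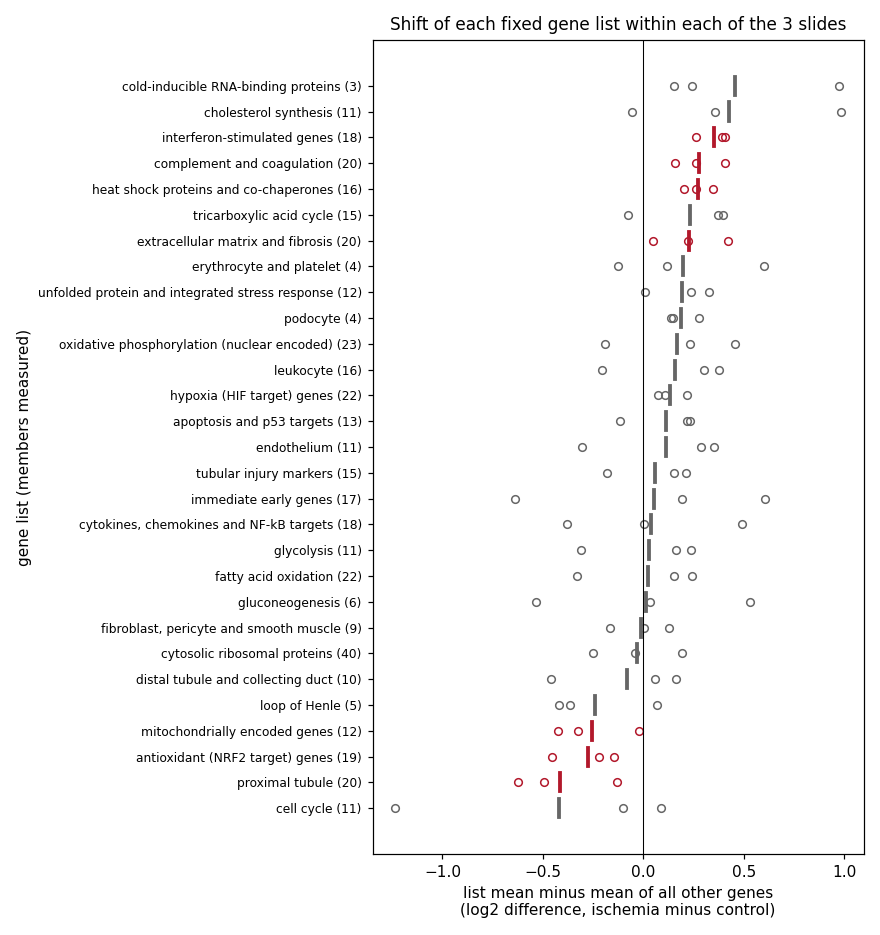
Shift of each of the 29 tested gene lists (y axis, measured members in brackets), as the mean log2 difference of the list minus that of all other genes (x axis). Bars are the shift over all 6 arrays and open circles the shifts within the 3 slides, each from 1 control and 1 ischemia array. The 7 lists in red passed camera at a preset correlation and have all 3 circles on one side of 0, as the hypoxia, podocyte, unfolded protein and cold-inducible lists in grey do.

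The other metabolic lists did not pass with the main settings, but camera passed nuclear encoded oxidative phosphorylation in 10 of 20 settings, the tricarboxylic acid cycle in 8 and cholesterol synthesis in 6. Nuclear encoded oxidative phosphorylation genes had 21 of 23 members higher and a shift of 0.17 (camera adjusted p = 0.0629), opposite in sign to the mitochondrially encoded genes. ATP5ME was at 0.52 ± 0.27 (SE) and NDUFA9 at 0.37 ± 0.25. Its within-slide shifts were 0.46, -0.19 and 0.23, and with slide as a block its camera adjusted p was 0.0331. The shift was 0.35 without ischemia 3 (camera adjusted p = 9.4e-05) and -6.6e-05 without ischemia 2 (0.925), and with an estimated correlation the adjusted p was 0.918. The tricarboxylic acid cycle had 13 of 15 members higher (shift 0.23, camera adjusted p = 0.0629, or 0.0331 with the block), with fumarase, FH, at 0.80 ± 0.26 and DLST at 0.40 ± 0.29. Its within-slide shifts were 0.39, -0.08 and 0.37, the shift was 0.40 without ischemia 3 (camera adjusted p = 0.00139) and 0.10 without ischemia 2 (0.419), and the adjusted p was 0.878 with an estimated correlation. Cholesterol synthesis had a shift of 0.43 (camera adjusted p = 0.0753, or 0.0117 with the block), with MVK at 0.91 ± 0.46 and NSDHL at 0.48 ± 0.27. Its within-slide shifts were 0.99, -0.06 and 0.36, and the adjusted p was 0.878 with an estimated correlation. The cholesterol shift was 0.86 without ischemia 3 (camera adjusted p = 8.9e-05) and 0.55 without control 3 (0.0344), but 0.08 without ischemia 2 (0.701) and 0.24 without control 2 (0.385). Fatty acid oxidation (shift 0.02, camera adjusted p = 0.905), glycolysis (0.03, 0.905) and gluconeogenesis (0.01, 0.849) lay near the other genes only on average. Their within-slide shifts went both ways. They were -0.33, 0.24 and 0.15 for fatty acid oxidation, 0.24, -0.31 and 0.16 for glycolysis, and -0.53, 0.53 and 0.04 for gluconeogenesis. ACADL was at 0.45 ± 0.27, ACADM at 0.30 ± 0.18, LDHB at 0.22 ± 0.30, PCK2 at -0.42 ± 0.39 and G6PC, the last enzyme of glucose release, at 0.95 ± 0.34. Cytosolic ribosomal proteins had a shift of -0.03 (camera adjusted p = 0.595), with RPS9 at 0.79 ± 0.34 and RPS19 at -0.40 ± 0.30. The probes of RPS9 and RPS19 were dim for this list, with control means of -2.21 and -1.86 against a mean log2 signal of 7.16 over the list. Their values are therefore uncertain.

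The other stress and injury lists showed no shift past the threshold with the main settings. Among hypoxia targets (shift 0.13, camera adjusted p = 0.488), ANGPTL4, an inhibitor of lipoprotein lipase, was at 1.83 ± 0.45 (SE) and the carbonic anhydrase CA9 at 0.81 ± 0.22, while VEGFA was at 0.06 ± 0.21. Immediate early genes (0.05, camera adjusted p = 0.649) had GADD45G at 0.66 ± 0.25 and FOS at -0.42 ± 0.50. EGR1 was at -1.31 ± 0.38 on its brighter probe and 0.20 on the other. The unfolded protein list (0.19, camera adjusted p = 0.152) had DDIT3 at 0.56 ± 0.28 and ATF4 at 0.42 ± 0.27. The apoptosis and p53 list (0.11, camera adjusted p = 0.499) had CDKN1A, the p21 inhibitor of cyclin-dependent kinases, at 1.14 ± 0.25. The cell cycle list had a shift of -0.42 (camera adjusted p = 0.0555, or 0.0432 with slide as a block), most of it on slide 2, where the shift was -1.24 against -0.10 and 0.09. Without ischemia 3 the cell cycle shift was -0.09 (camera adjusted p = 0.761), and it was -0.62 without ischemia 2 (0.00527), -0.54 without ischemia 1 (0.0197) and -0.54 without control 3 (0.0283). The list passed camera in 9 of 20 settings, and its adjusted p was 0.878 with an estimated correlation. CCNB2 was not well above background on any ischemia array. Its plain estimate was 2.34-fold lower, and the bound for dim probes equalled it. Its groups overlapped, with a plain log2 difference of -1.22 ± 0.46, and CCNB1 was at -0.84 ± 0.47. The cold-inducible list (0.46, camera adjusted p = 0.0753) had CIRBP at 0.70 ± 0.33 and RBM5 at 0.55 ± 0.25, and its shift was 0.64 without ischemia 2 (camera adjusted p = 0.0112) and 0.21 without ischemia 3 (0.549). Cytokines and NF-kB targets (0.04, camera adjusted p = 0.849) had CXCL10 at 0.77 ± 0.29 and IL1B, not well above background on any control array, at least 2.85-fold higher. The plain log2 difference of IL1B was 1.84 ± 0.48. Tubular injury markers (0.06, camera adjusted p = 0.669) had VCAM1 at 0.51 ± 0.19 and TIMP2 at 0.44 ± 0.23. LCN2, the NGAL injury marker, was at 0.03 ± 0.52 on its brighter probe and -0.06 on the other, and the inducible HSP70 gene HSPA1A at 0.45 ± 0.38. No probe named here carried HAVCR1, and ATF3, IL6 and CXCL8 were too dim to be tested. For the cytokine and gluconeogenesis lists the mean lay above the other genes while the median and the test pointed lower, and for the fibroblast list the mean lay below them while the median and the test pointed higher.

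Markers of the other cell types of the cortex did not pass with the main settings. Loop of Henle markers had a shift of -0.24 (camera adjusted p = 0.239), with CLDN19 at -0.48 ± 0.33 (SE) and EGF at -0.27 ± 0.27. Distal tubule and collecting duct markers had a shift of -0.08 (camera adjusted p = 0.464), with HSD11B2 at -0.62 ± 0.31 and AQP2 at -0.41 ± 0.23. Podocyte (0.19, camera adjusted p = 0.575), endothelial (0.11, 0.499) and fibroblast and smooth muscle markers (-0.01, 0.788) included WT1 at 0.69 ± 0.36, TEK at 0.78 ± 0.29, NOS3 at 0.30 ± 0.37 and CNN1 at 0.92 ± 0.37. Leukocyte markers had a shift of 0.16 (camera adjusted p = 0.344), with CD163, a scavenger receptor of macrophages, at 1.42 ± 0.32 and FCER1G at 0.49 ± 0.24. Of its 16 members 10 were higher and 6 lower. Among the lower was PTPRC, the CD45 antigen of all leukocytes, at -0.47 ± 0.24 on its brighter probe and -0.13 on the other. On the brighter probe all ischemia values lay below all control values, though the difference on slide 1 was only -0.0026. CD14, a monocyte receptor, was at -0.42 ± 0.26 on its brighter probe and 0.34 on the other. Without ischemia 1 the leukocyte shift was 0.27 and passed (camera adjusted p = 0.0200), and without ischemia 2 it was 0.05 (0.786). Erythrocyte and platelet markers (0.20, camera adjusted p = 0.804) had GP9 at -0.23 ± 0.18 and ITGA2B at 0.24 ± 0.22. The metallothioneins had 2 tested genes, too few for a list test, with MT1A at -0.52 ± 0.43 and MT3 at 0.29 ± 0.32. Of the Y-linked genes and XIST, 1 was tested, UTY, at -0.65 ± 0.20, and it was well above background on 3 control arrays and 1 ischemia array. The sex of the animals is not given in the sources used here, so the groups may differ in it.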

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

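The gene-by-gene array weights were chosen only after the results were seen, because the default weights did not converge and gave control 2 a weight of 390.1 against under 1 for the others. The other alternatives were planned. The count of 1 probe became 11 with median centring, 3 with normexp, with normexp and quantile normalization, in the deposited values, with the filter on all 6 arrays and with the variance trend, 868 with array weights and 21 with the gene-by-gene weights (weight 8.66 for control 2). It was 0 with quantile normalization, without the filter and with the slide block, and 0 to 1 with 1 array left out (0 without control 1, control 2 or ischemia 2). The count of genes higher was 83 with array weights and 0 in the other settings. The count of genes lower, 0, became 2 with median centring, 1 with normexp, 78 with array weights, 4 with the gene-by-gene weights and 0 to 1 with 1 array left out (1 without ischemia 3). The count of 7 lists became 11 with the slide block and with the gene-by-gene weights, 0 with an estimated correlation and 0 with fry, and 5 to 11 with 1 array left out (11 without ischemia 3). All 7 kept their sign in every setting run. The cause was not tested for these changes.

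Samples with the same number did not deviate together (correlations -0.35, -0.17 and -0.05), so the number is not taken to pair them. With the replicate block 0 probes and 10 lists passed. Arrays on the same slide correlated at 0.34, 0.10 and 0.33.

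Values not past the threshold with the main settings changed sign as follows, and the cause was not tested. With the default and the gene-by-gene weights, the shifts were -0.091 and -0.052 for immediate early genes, -0.028 and -0.022 for fatty acid oxidation, -0.093 and -0.075 for gluconeogenesis, and 0.078 and 0.046 for the distal tubule. Under the same weights MT1A was at 0.38 and 0.25 and LCN2 at -0.14 and -0.11. With normexp, cytokines were at -0.032, the fibroblast list at 0.10 and LCN2 at -0.079. With normexp and quantile normalization, ribosomal proteins were at 0.034 and the fibroblast list at 0.11. With quantile normalization, ribosomal proteins were at 0.020. In the deposited values the fibroblast list was at 0.16, GP9 at 0.041 and CD14 at 0.080. Without the filter the fibroblast list was at 0.019 and the erythrocyte list at -0.0039. With the filter on all 6 arrays the fibroblast list was at 0.013 and cytokines at -0.080. With the mean of all probes the fibroblast list was at 0.030 and LCN2 at -0.012. With 1 array left out, the ranges were -0.25 to 0.34 for immediate early genes, -0.14 to 0.17 for cytokines, -0.072 to 0.17 for injury markers, -6.6e-05 to 0.35 for nuclear oxidative phosphorylation, -0.10 to 0.17 for fatty acid oxidation, -0.14 to 0.22 for glycolysis, -0.27 to 0.23 for gluconeogenesis, -0.15 to 0.087 for ribosomal proteins, -0.21 to 0.16 for the distal tubule, -0.019 to 0.31 for endothelium, -0.081 to 0.054 for the fibroblast list, -0.14 to 0.57 for the erythrocyte list, -0.022 to 0.69 for NOS3, -0.56 to 0.53 for LCN2 and -0.042 to 0.18 for VEGFA. Some lists passed camera only with 1 array left out. Immediate early genes passed without ischemia 1 (adjusted p = 0.0136), leukocyte markers without ischemia 1 (0.0200), endothelium without ischemia 2 (0.00855), cold-inducible genes without ischemia 2 (0.0112) and ribosomal proteins without ischemia 3 (0.0234). The unfolded protein list passed without ischemia 3 (0.0147) and with normexp (0.0499). Nuclear oxidative phosphorylation passed with quantile normalization (0.0175), normexp (0.00469), in the deposited values (0.00872) and without the filter (0.0311), among others.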

Other observations

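The tests of array position, of proximal tubule share, of leukocyte share, of a single animal, of the slides, of the brightest genes, of the mitochondrial list against random lists, of the slide-balanced splits and of the solute carriers without SLC28A1 were chosen only after the results they measure were seen. The tests of the proximal tubule and interferon lists against random lists, of the wider set of bright genes, of all other splits and of the solute carrier class were written down before their values were seen, although seeing SLC28A1 and SLC22A6 low prompted the last.

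Solute carrier genes outside the fixed lists tended lower after ischemia. Of 97 genes whose symbol starts with SLC, 63 were lower and 34 higher, with a mean -0.18 from that of the other genes (camera p = 6.59e-04 at the preset correlation). SLC28A1 prompted the test. With it left out, the other 96 solute carrier genes had a mean shift of -0.16, and the limma camera p was 0.00174. With an estimated correlation the p was 0.214 with SLC28A1 and 0.239 without it, so the shift may reflect genes that vary together between animals.

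Proximal tubule markers lay lower after ischemia. None of 10000 random lists matched on signal had a mean as low (percentile 0), which argues against the brightness of the probes. A smaller share of proximal tubule in the ischemia samples stays open, since it would raise markers of every other type alike. Loop of Henle markers lay -0.35 from the 40 markers of podocytes, endothelium, fibroblasts and leukocytes, but this was not beyond chance (permutation p = 0.110, two-sided, over genes, which are not independent replicates). Array position stays open as well, since the number of positions holding both groups was 0. An effect of the warm ischemia, flush or cold storage, which cannot be separated here, is one more possible explanation.

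Interferon-stimulated genes lay higher after ischemia. The list mean was at percentile 99.8 of random lists matched on signal, which argues against brightness, and the lowest shift with 1 array left out was 0.33 against 0.35 with all arrays, which argues against a single animal. More leukocytes in the ischemia samples stay open. The 16 leukocyte markers lay -0.20 from the interferon-stimulated genes (permutation p = 0.154, two-sided, over genes, which are not independent replicates). Of these markers 6 were lower after ischemia, though none of the 6 passed. PTPRC was among them, at -0.47 ± 0.24 (SE) on its brighter probe and -0.13 on the other. The leukocyte shift was 0.27 without ischemia 1, where the list passed, and 0.05 without ischemia 2. Array position is confounded here too, and an effect of the warm ischemia, flush or cold storage stays open.

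Mitochondrially encoded genes lay lower while nuclear encoded oxidative phosphorylation genes lay higher, though the latter list did not pass. The mitochondrial minus nuclear difference was -0.48, -0.14 and -0.66 within the 3 slides (mean -0.42, SE 0.15). A difference between slides shared by both groups cancels by design, since each slide held 1 array of each group. The within-slide values could not have shown it, so they do not test it. With slide as a block the shifts of -0.26 and 0.17 had camera adjusted p of 0.00382 and 0.0331. Variation between animals stays open, since the mitochondrial shift was -0.02 on slide 1, the nuclear shift was -0.19 on slide 2, and the nuclear shift was -6.6e-05 without ischemia 2. Array position is confounded here too, an effect of the warm ischemia, flush or cold storage stays open, and brightness does as well. With quantile normalization, which gives all arrays the same distribution of signal, the mitochondrial shift went from -0.26 to -0.14 and its call was lost (camera adjusted p = 0.0925). The mitochondrial mean was at percentile 0.76 of random lists matched on signal, which speaks against it, but the matched genes were dimmer (mean log2 signal 7.31 against 7.87), since few genes are as bright. A first test set these genes against 3202 others brighter than the dimmest of them, with a median log2 difference of 0.032. That lay above the third quartile of the mitochondrially encoded genes (-0.23), which by the rule written beforehand speaks against brightness. The set of 3202 held most genes on the array, however, and so diluted the bright ones. A narrower set was chosen after that value was seen. It held 32 other genes at or above the median signal of the mitochondrially encoded ones and had a median of -0.18. The mitochondrial mean lay only -0.06 from the mean of this set (permutation p = 0.182, two-sided, over genes, which are not independent replicates). The mitochondrial mean also took in members dimmer than this set, so brightness was not matched. The low values could still belong to the brightest probes in general.

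With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 probe past the threshold and the highest of the others 1, and 2 of 10 splits gave as many. For named genes the real split gave 0 higher and 0 lower, and the highest of the others 0 and 0. All 10 splits reach a count of 0 by construction, so this comparison carries no information. It gave 7 lists, and the highest of the others 10, and 7 of the 10 splits gave at least as many. At unadjusted p under 0.05 the real split gave 1574 probes, and the split of control 1, ischemia 2 and ischemia 3 against the rest gave 3710, which points to a structure of the samples. That split puts both arrays of slide 1 on one side and both arrays of slide 3 on the other. In the 4 splits with 1 array of each slide on each side, the real one gave 1574 such probes and 7 lists, and the others 361 to 563 probes and 6 to 10 lists.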
